A study of Mus musculus with 6 samples.

How the data were processed

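RNA was measured by sequencing in 6 libraries of mouse corpus callosum, the main tract of axons between the cortical hemispheres, taken on postnatal day 4. Per the labels' protocols, the tract was dissected by hand from frozen brain sections, polyadenylated RNA was isolated on beads, and libraries were made with a kit that does not mark strand. Group and replicate number came from the sample titles: 3 WT libraries and 3 libraries from a conditional knockout (cKO) of Mettl14, a subunit of the enzyme complex that writes N6-methyladenosine (m6A) on RNA. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these libraries.

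The authors deposited 1 RSEM table of transcripts per library. STAR 2.7.10b and RSEM 1.3.3 with build mm10 are named per the submitters' processing notes; the annotation release, strand setting and filters are not given in the sources used here. Per the file headers, the deposited expected counts are estimated numbers of fragments per transcript and need not be whole. The deposited TPM values, per the file headers, are scaled to transcript length and library total, and were used, after adding 1 and taking log2, only in an alternative test. The effective length of other deposited columns, per the file headers, was used only to read each library's mean fragment length.

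The files held 35034 transcripts of 24411 genes and 0 mitochondrial genes. Expected counts were summed per gene and rounded to whole numbers. Symbols, exon numbers and positions were taken from a RefSeq gene table and an annotation of GRCm38, the same assembly as mm10. By accession 24161 genes were matched, 157 were matched by symbol and 93 stayed unmatched; 1136 genes carry a newer symbol than in the files. Without strand, reads from a gene and an overlapping antisense gene cannot be told apart, and paralogs such as the tubulin and globin genes share reads that RSEM divides by estimate.

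Total expected counts were 843647, 1268430 and 860073 in WT replicates 1 to 3 and 852115, 1208382 and 670462 in the cKO replicates. On the TMM scale used here 1 count equals 0.803 to 1.41 CPM, and 3 counts, the upper limit that a count of 0 allows, equal 2.41 to 4.24 CPM per library. Mean fragment length was 304.3 bases in WT replicate 2 and 292.7 in cKO replicate 2, against 332.4 to 350.5 in the others, so both replicate 2 libraries share a larger depth and shorter fragments. No pair of libraries matched within counting noise. Counting intervals and floors cover counting error only.

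The main test was edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr with its minimum count of 10) in R 4.3.3, cKO against WT over all 6 libraries with no covariate. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the 5918 genes tested. CPM uses the same scaling, and fold changes are cKO relative to WT. Where a group's total was 0, a fold is a bound computed with 3 counts over that group. Where it was 1 to 3, the ratio of pooled counts is given with an exact 95% counting interval. Elsewhere log2 fold changes are given with an approximate standard error (SE). It was worked back as the absolute log2 fold change over the square root of the test's F statistic. It thus restates the p-value and is not a separate measure of spread. Mettl14 and Mettl3 lay below the filter and were fitted with the same scaling outside the tests.

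Before the data were examined, 37 gene lists were fixed, 7 of them as primary lists for RNA in axons; 33 had at least 3 tested members. Some genes stand on several lists. The lists were tested with camera in limma 3.58.1 (preset correlation 0.01, competitive), adjusted over the tested lists, and again with an estimated correlation. The lists of mitochondrial, interferon-response, sex-linked and choroid plexus genes had too few tested members. The rule for named genes, fixed at the same time, takes Mettl14 and Mettl3. It adds, per direction, the 15 protein-coding called genes with the largest change, a mean of at least 5 CPM and groups that do not overlap. It also takes up to 4 tested members per discussed list with the smallest p and the most abundant member of each primary list. Ddx3y, Uty, Kdm5d, Neurod6, Gfap, Sox11, Zbtb18, Islr2, Dab1, Mt3 and Dbi were named after their values were seen. Some genes that the rule takes are not reported here.

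Alternatives were RLE and upper-quartile scaling, other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), unrounded counts, the replicate number as a block, other thresholds, and leaving out each library in turn. Added after seeing the data were fits without both replicate 2 libraries, with depth batch or loss of few-exon genes as a term, on counts thinned to equal depth, and on subsets of genes, and an estimated correlation for lists that passed only under an alternative. The test was tried on simulated data with the real means, depths and dispersions and 200 changed genes. Over 5631 simulated genes that passed the filter it recovered 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 26 of 50 changed 16-fold and 41 of 50 changed 64-fold, with 6 false calls among 73. With no gene changed it made 0 calls among 5682 genes, while 4.51% had an unadjusted p below 0.05. The simulated genes varied independently, without loss of few-exon genes or the depth batch, so false calls from such effects were not tried.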

Results

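The series asks how m6A bears on the movement of neuronal mRNA from cell bodies to neurites. RNA from the corpus callosum of WT and Mettl14 cKO mice was compared on postnatal day 4, with 3 libraries per group. Depth was low, from 670462 to 1268430 expected counts per library, and 10113 to 11110 genes had a count above 0. The ribosomal RNA gene Rn45s took 1.26% to 2.79% of the counts. Across all genes, which are not independent replicates, log CPM correlated with r of 0.681 to 0.808 among WT libraries, 0.641 to 0.793 among cKO libraries and 0.564 to 0.746 between the groups. WT replicate 2 correlated more closely with cKO replicate 2 (0.746) than with WT replicate 1 (0.681). Over the 168 genes with the highest mean CPM over all 6 libraries, r was 0.971 to 0.979 among WT libraries. It was 0.954 between cKO replicates 1 and 2, and 0.623 and 0.6 between these and cKO replicate 3. Between the groups it was 0.138 to 0.298. Neurod2 and Xist, at 0 CPM in WT, are among these genes. Such genes can lower the r between the groups and raise the r within a group.

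Mettl14 (chromosome 3, 123368295 to 123385990, GRCm38), the targeted gene, had 11, 8 and 5 counts in the WT libraries and 2, 7 and 2 in the cKO libraries. Pooled counts were 1.79-fold lower in cKO with a 95% counting interval of 0.842 to 4.04, and the fitted log2 fold change was −0.88 (SE 0.55). An exact two-sided permutation test of CPM gave p = 0.3, where 3 libraries against 3 cannot go below 0.1. Its partner Mettl3, the catalytic subunit, had 11, 8 and 3 counts in WT and 1, 6 and 3 in cKO, with a log2 fold change of −0.87 (SE 0.66). A loss of Mettl14 was not detectable at this depth. Reads outside a deleted part, or from cells without the deletion, would also be counted.

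Between the groups, 29 genes were higher and 25 were lower in cKO among 5918 tested (edgeR quasi-likelihood, adjusted p below 0.05). Mbp and Bcas1, transcripts of oligodendrocytes, the myelin-forming glia, had 1170 and 2043 times lower pooled counts in cKO, with 2 and 1 counts over its libraries. Neurod2 and Pou3f1, transcription factors of forebrain neurons, had 0 counts over the WT libraries and 197 to 1996 in each cKO library. Xist was counted in the cKO libraries only and Y-linked genes in the WT libraries only, so each difference between the genotypes is also one between these. All 54 called genes had groups that did not overlap, as had 19.8% of all tested genes, where chance gives 10%. Of the called genes, 16 higher ones had at most 3 counts over the WT libraries and 9 lower ones at most 3 over the cKO libraries. Leaving out WT replicate 3 or cKO replicate 1 left 0 genes in either direction with edgeR (573 and 591 genes at an unadjusted p below 0.05; no other tool was run on those subsets), and higher and lower counts were 1 and 0 without WT replicate 1, 13 and 8 without WT replicate 2, 6 and 4 without cKO replicate 2, and 28 and 14 without cKO replicate 3. Of these, 7 and 7 without WT replicate 2 and 9 and 10 without cKO replicate 3 were among the 29 and 25. Both replicate 2 libraries share a larger depth and shorter fragments; with this batch as a term, chosen after seeing the data, 11 and 8 genes were called (10 and 8 shared), and with both left out 0 and 0 (edgeR, 740 genes at an unadjusted p below 0.05; no other tool was run on that subset). DESeq2 on all 6 libraries called 250 higher and 179 lower. Without a filter, or with a filter of 1 CPM in 3 libraries, edgeR called 12 higher and 10 lower. With the replicate number as a block it called 1 higher and 0 lower (763 genes at an unadjusted p below 0.05, and no other tool was run with the block).

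Mbp, myelin basic protein (chromosome 18, 82475091 to 82585637), fell from 993 ± 288 CPM in WT to 0.943 ± 1.63 in cKO (SD, n = 3; edgeR adjusted p = 0.0147), a ratio of 1170 with a counting interval of 324 to 9662. Bcas1, expressed in newly forming oligodendrocytes (chromosome 2, 170343973 to 170427911), had 924, 854 and 719 counts in WT and 0, 1 and 0 in cKO, a ratio of 2043 (interval 366 to 80720). Mbp has 7 exons and Bcas1 has 13. Cnp, a myelin enzyme, fell by 7.23 on the log2 scale (SE 0.89). Myrf, a transcription factor of myelin genes, and Enpp6 were at 0 in cKO and at least 15.5-fold and 13.9-fold lower. Of 8 tested markers of myelinating oligodendrocytes 7 fell and 8 were lower when adjusted over the list alone, with a median log2 fold change of −7.19 and of −5.6 with genes at 0 set at their bound. The list stood below other genes (camera adjusted p = 1.22e-39) and did so with an estimated correlation (adjusted p = 0.0159).

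Other glial and progenitor transcripts were lower too. Aldoc, an astrocyte enzyme of glycolysis, fell from 748 ± 13.04 to 30.8 ± 1.76 CPM (SD, n = 3), a log2 fold change of −4.59 (SE 0.33, edgeR adjusted p = 0.00664). The lipid carrier Apoe fell by 1.57 (SE 0.16) on the log2 scale. All 16 tested astrocyte markers had negative values, 2 of them past the threshold and 9 when adjusted over the list alone (median −2.01; camera adjusted p = 1.64e-14, and 0.0164 with an estimated correlation). Gfap did not pass, with 40, 47 and 729 counts in cKO replicates 1 to 3. Pdgfra, the receptor of oligodendrocyte precursors, fell by 5.39 (SE 0.49), while Ptprz1 at −1.65 (SE 0.33) and Matn4, at least 43.1-fold lower, did not pass. Of 8 tested precursor markers 1 fell and 4 were lower when adjusted over the list alone (median −1.53; camera adjusted p = 2.3e-08, but p = 0.0711 with an estimated correlation).

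Among 22 tested proliferation genes, each with a negative value, the cyclin Ccna2 fell by 4.87 (SE 0.66) and 9 were lower when adjusted over the list alone. The list's median was −1.36 (camera adjusted p = 6.69e-11, and 0.0299 with an estimated correlation). Fabp7, a lipid-binding protein of radial glia, fell by 1.7 (SE 0.24). Of 14 tested radial glia markers 13 had negative values, 1 past the threshold and 6 when adjusted over the list alone (median −1.56; camera adjusted p = 3.49e-06, and p = 0.0502 with an estimated correlation). Gpr37l1, a glial receptor, had 361, 342 and 329 counts in WT and 0 in each cKO library, at least 281-fold lower. Ednrb, the endothelin receptor B, fell by 4.86 (SE 0.75), S100a16 was at least 133-fold lower, and Lims2 and Plxnb3 also fell.

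**Figure D1:**
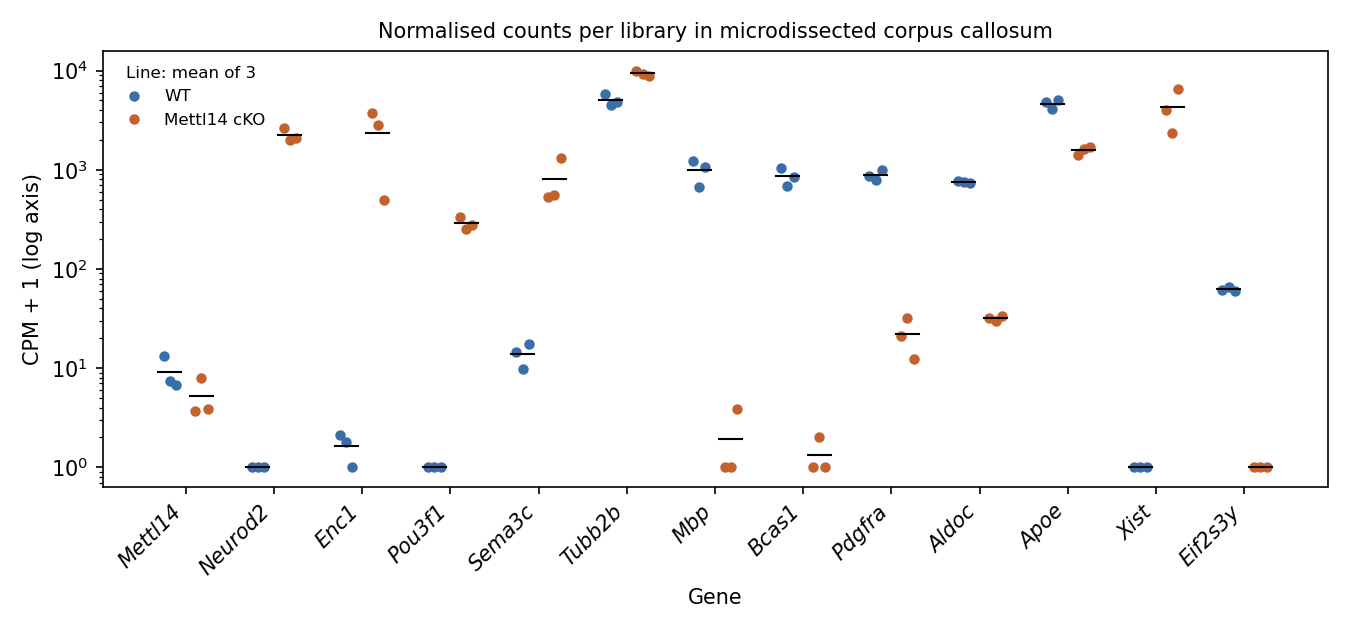
Normalised counts of 13 genes in each library (vertical axis: CPM + 1 on a log axis; points: libraries; lines: means of 3; blue: WT, orange: Mettl14 cKO). Neurod2, Pou3f1 and Xist lie at 0 CPM in the 3 WT libraries and Eif2s3y at 0 in the 3 cKO libraries, while Mettl14 overlaps between the groups.

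Neurod2, a factor of cortical excitatory neurons (chromosome 11, 98325415 to 98329645), had 0 counts in each WT library and 1973, 1996 and 1470 in cKO, at least 2216-fold higher (edgeR adjusted p = 0.00664). Pou3f1 rose from 0 to 249, 249 and 197. Id2, an inhibitor of basic helix-loop-helix factors, was at least 487-fold higher, and Enc1, an actin-binding protein of neurons, had 2 counts over WT and 2779, 2841 and 349 in cKO, a ratio of 3648 (counting interval 1009 to 30130). Sox11 rose by 2.51 (SE 0.27) and Zbtb18 by 2.41 (SE 0.27), both factors of developing neurons. Zfp292 rose by 7.69 (SE 1.04) and Hs6st2 by 6.57 (SE 0.8). Slc25a51, Msantd3, Llph, Rab33a, Zbtb33, Med4, Sumo3 and Rpp25l, each at 0 to 3 counts over the WT libraries, rose as well; Hs6st2, Rab33a and Zbtb33 lie on the X chromosome. Of these higher genes, Zfp292, Hs6st2, Med4 and Sumo3 have more than 3 exons. The others have 1 to 3, and genes with so few exons were at 0 or 1 count more often in WT replicates 1 and 3 and cKO replicate 3 than in the other libraries. Some genes with more than 3 exons were at 0 or 1 count too, from 0.218% in WT replicate 2 to 2.14% in cKO replicate 3. More than 3 exons alone thus does not show that a low WT count reflects expression.

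Neuronal lists were less uniform than these genes. Of 15 tested excitatory neuron markers 12 had positive values and 1, Neurod2, rose, also when adjusted over the list alone (median 1.04; camera adjusted p = 3.53e-06, but p = 0.17 with an estimated correlation). Bhlhe22 at 6.03 (SE 1.77) and Neurod6 at 4.72 (SE 1.8) did not pass. For upper-layer neurons, which send many axons through the callosum, 1 of 15 rose and 6 were higher and 1 lower when adjusted over the list alone (median 0.51; camera adjusted p = 0.0101, p = 0.145 with an estimated correlation). The 10 deep-layer markers had a median of −0.8 and a camera adjusted p of 0.39. Neuron markers with 1 to 3 exons had a median of 6.15 over 6 genes and those with more exons 0.51 over 23 genes.

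Among lists chosen for RNA in axons, axon guidance was the one past the threshold (camera adjusted p = 8.93e-07), but adjusted p = 0.077 with an estimated correlation. Sema3c, a secreted guidance cue, rose by 5.95 (SE 0.59, edgeR adjusted p = 0.0147), and 10 of 37 tested members were higher when adjusted over the list alone. Efnb1 at 4.83 (SE 0.78), Cntn2 at 4.38 (SE 0.84) and Plxna2 at 2.2 (SE 0.45) did not pass over all genes. The list's median was 1.14. Of 54 axon cytoskeleton genes Tubb2b, a tubulin of growing neurons, rose by 0.9 (SE 0.13, edgeR adjusted p = 0.0361) and 2 were higher when adjusted over the list alone, with a camera adjusted p of 0.104. The call of Tubb2b depended on the scaling and the filter, with 0.58 and an edgeR adjusted p of 0.761 with upper-quartile scaling, an adjusted p of 0.178 without a filter, and 1.74e-06 to 0.761 over all alternatives. Basp1 at 1.24 (SE 0.21), Tubb3 at 0.87 (SE 0.2), Dcx at 1.06 (SE 0.26) and Tuba1a at 0.36 (SE 0.18) did not pass. Without WT replicate 1 or cKO replicate 3 the cytoskeleton list passed (camera adjusted p = 0.034 and 0.00024), but with an estimated correlation in the same fits adjusted p = 0.607 and 0.419.

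Ribosomal and respiratory chain genes held no call. With edgeR 0 of 78 ribosomal protein genes passed, 0 at an unadjusted p below 0.05 and 0 with DESeq2 or limma-voom (median −0.04, mean 0.03, camera direction down, adjusted p = 0.631), and Rplp0 had a log2 fold change of 0.03 (SE 0.24). Of 62 respiratory chain genes 0 passed with edgeR, 1 at an unadjusted p below 0.05 and 0 with DESeq2 or limma-voom (median 0.01, mean 0.19, camera direction down, adjusted p = 0.587), while without cKO replicate 3 the list was called up (adjusted p = 0.0212, but p = 0.175 with an estimated correlation). The 44 transport motor genes had a median of 0.05, −0.02 relative to all genes, with camera direction down (adjusted p = 0.631), and Kif1a, a kinesin of synaptic vesicle precursors, stood at −0.83 (SE 0.24). The 40 presynaptic genes had a median of 0.08 (adjusted p = 0.631), 1 of them higher when adjusted over the list alone. Of 60 mRNAs bound by FMRP, the fragile X protein, Bcan, a proteoglycan of the brain matrix, fell by 1.89 (SE 0.25), also when adjusted over the list alone, and the camera adjusted p was 0.105 (median 0.58).

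**Figure D2:**
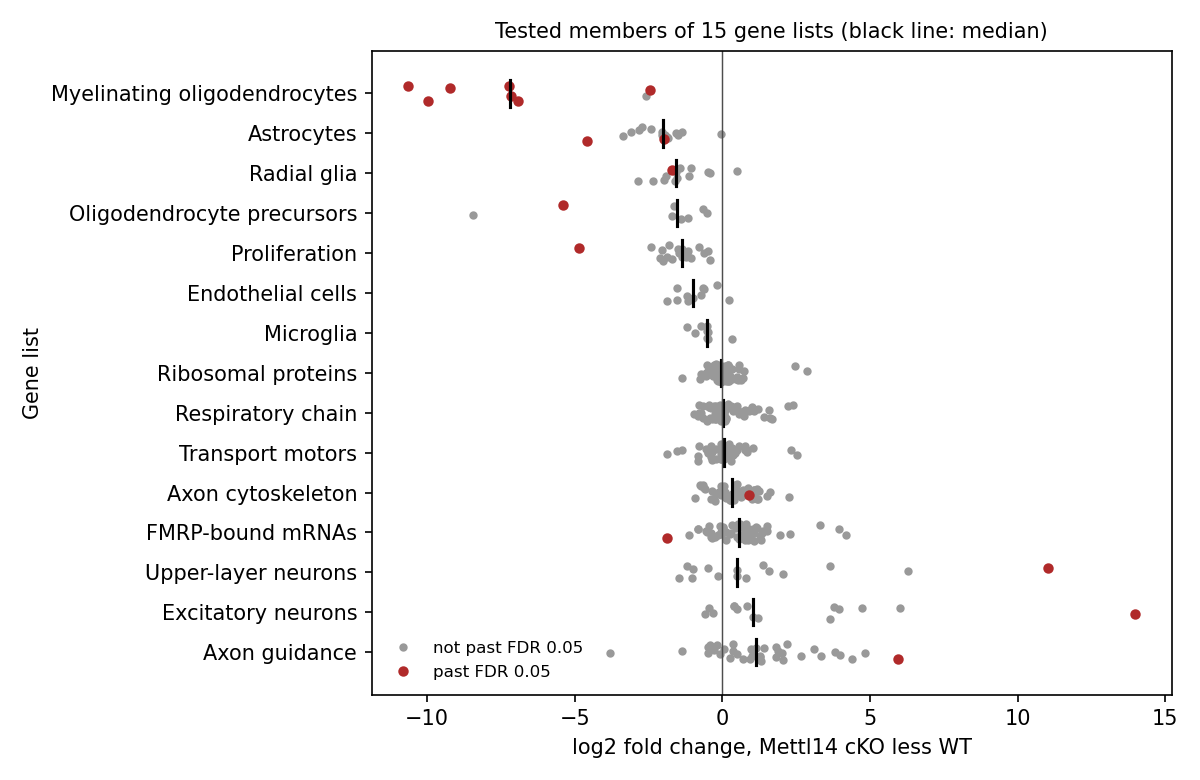
Log2 fold changes of the tested members of 15 gene lists (horizontal axis: cKO less WT; points: genes, red where the adjusted p is below 0.05; black lines: list medians). Myelinating oligodendrocyte markers lie around a median of −7.19 and axon guidance genes around 1.14; values of genes with 0 counts in a group depend on the fit's prior count.

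Endothelial markers (11 tested, median −0.99, camera adjusted p = 0.00175) and white-matter microglia genes (7 tested, median −0.45, camera adjusted p = 0.0101) stood lower as lists, but with an estimated correlation adjusted p = 0.146 and 0.145; 1 member of each was lower when adjusted over the list alone, for the latter Apoe. Over all genes edgeR and limma-voom called 0 endothelial markers and DESeq2 1, and 4 had an unadjusted p below 0.05. Without cKO replicate 1 or 2 the white-matter microglia list did not pass (adjusted p = 0.0509 and 0.0815). Glycolysis and hypoxia genes (20 tested, median −0.38, camera adjusted p = 0.0101) had an adjusted p = 0.423 with an estimated correlation. Their 1 gene that fell was Aldoc, 1 was higher and 1 lower when adjusted over the list alone, and the list did not pass without WT replicate 2 or cKO replicate 3 (adjusted p = 0.104 and 0.225). Of 3 meningeal fibroblast markers Pdgfra, shared with precursors, was the 1 that fell, also when adjusted over the list alone (median −0.3, mean −1.59, camera adjusted p = 0.00886, but adjusted p = 0.145 with an estimated correlation). That list did not pass without WT replicate 2, WT replicate 3 or cKO replicate 2 (adjusted p = 0.0798, 0.105 and 0.0628). The m6A demethylases and readers stood higher as a list (12 tested, median 0.27, mean 1.11, adjusted p = 0.0332, and p = 0.17 with an estimated correlation), with 2 members higher when adjusted over the list alone. Over all genes edgeR and limma-voom called 0 of them and DESeq2 4, and 4 had an unadjusted p below 0.05. The list did not pass without WT replicate 2, cKO replicate 1 or cKO replicate 3 (adjusted p = 0.0884, 0.0663 and 0.123). Among them Fmr1 stood at 2.5 (SE 0.62) and Ythdc1 at 1.72 (SE 0.53). Camera adjusted p was 0.304 for m6A writers (median 1.58), 0.198 for microglia, 0.0909 for mural cells, 0.105 for interneurons (median −1.33), 0.631 for striatal and 0.316 for hippocampal neurons, the last with a median of −0.25 and a mean of 1.41. Without WT replicate 1 or cKO replicate 3 microglia passed (adjusted p = 0.00433 and 0.0205), as did interneurons without WT replicate 3, cKO replicate 1 or cKO replicate 2 (0.0108, 0.0293 and 0.000887). With an estimated correlation in the same fits adjusted p = 0.35 and 0.419 for microglia and 0.356, 0.402 and 0.189 for interneurons. With a filter of 1 CPM in 3 libraries microglia, mural cells and interneurons passed (camera adjusted p = 0.0361, 0.0139 and 0.0229), as did axon cytoskeleton and FMRP-bound mRNAs (0.0277 and 0.0229). With that filter and an estimated correlation adjusted p = 0.429, 0.176, 0.176, 0.607 and 0.177 for these lists in the same order. On the interneuron list Cd24a, a surface protein of young neurons, rose by 1.74 (SE 0.23), and stood at 1.44 without passing with upper-quartile scaling (edgeR adjusted p = 0.288, the highest over its alternatives, the lowest being 4.53e-13). Adjusted over the list alone, 2 mural markers were lower, and 1 interneuron, 2 striatal, 1 hippocampal and 1 immediate early gene were higher. The camera adjusted p was 0.381 for RNA granule proteins, 0.222 for p53 targets, 0.321 for the stress response, 0.32 for immediate early genes, 0.405 for cholesterol synthesis, 0.811 for nuclear RNAs (median 0.03, mean −0.08) and 0.912 for erythroid genes (median 0.07, camera direction down). Upper-quartile scaling moved the median of all genes from 0.069 to −0.22 on the log2 scale; relative to that median, myelinating oligodendrocyte markers stood at −7.26 with TMM and −7.31 with upper-quartile scaling, and axon guidance at 1.08 and 1.24. With that scaling Apoe at −1.86, Bcan at −2.2 and Fabp7 at −2.09 did not pass (edgeR adjusted p = 0.0992, 0.0537 and 0.0548, with 1.77e-22 to 0.15, 5.82e-13 to 0.197 and 6.83e-11 to 0.223 over their alternatives).

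The genotypes also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome (chromosome X, 103460373 to 103483233), had 0 counts in the WT libraries and 2970, 2323 and 4618 in cKO. The Y-linked Eif2s3y had 54, 80 and 51 counts in WT and 0 in cKO, and Ddx3y, Uty and Kdm5d also had counts in WT only. Of the higher genes 6 lie on X, which holds 3.46% of tested genes, and 3 of these 6 have 1 to 3 exons. Of the 54 called genes 9 (16.7%) lie on X or Y. Restricted to autosomes, 23 genes rose and 20 fell. Sex and genotype cannot be told apart with these libraries.

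Genes with few exons were lost from single libraries. Of 315 tested genes with 1 to 3 exons, 29.2% had at most 1 count in WT replicate 1 (exact 95% interval 24.2 to 34.6), 23.2% in WT replicate 3 and 18.7% in cKO replicate 3. The shares were 7.62%, 4.76% and 2.54% in WT replicate 2 and cKO replicates 1 and 2. Such genes made up 16 of the 29 higher genes and 4 of the 25 lower, against 5.4% of tested genes (Fisher's exact test, p = 1.29e-13 and 0.043), with Neurod2, Id2, Enc1, Pou3f1 and Cd24a among the higher ones and Gpr37l1, S100a16 and Fabp7 among the lower ones. Fisher's test takes genes as independent, but few-exon genes were low together in the same libraries, so its p-values overstate the evidence. With genes of more than 3 exons only, 12 rose and 18 fell, and with this loss as a term in the fit 11 rose and 7 fell.

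**Figure D3:**
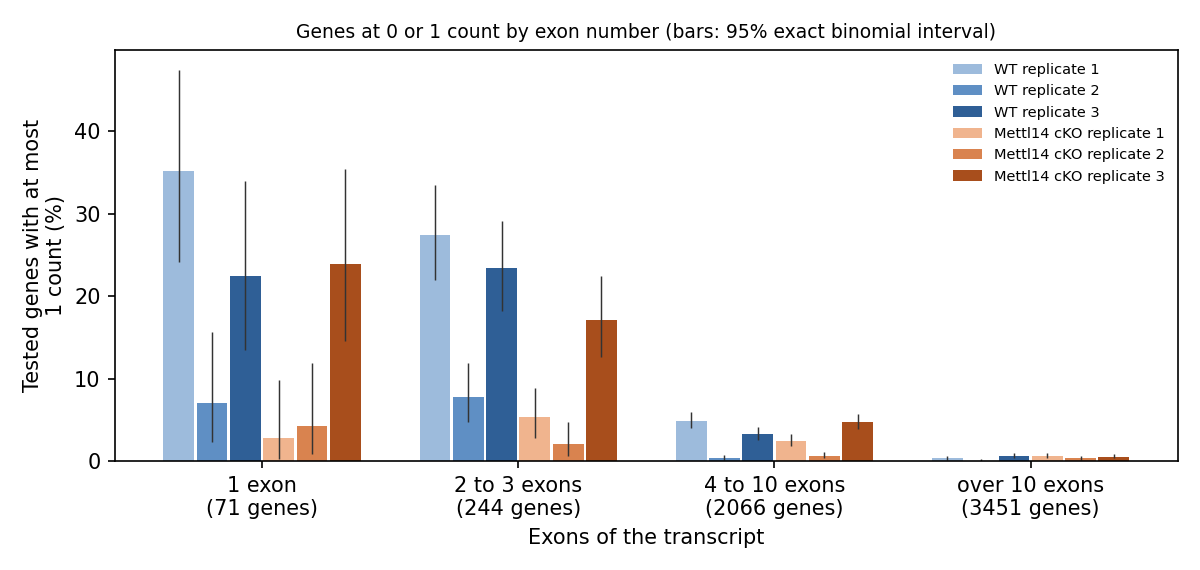
Share of tested genes with at most 1 count by exon number (vertical axis: percent; bars: libraries, blue WT and orange Mettl14 cKO; lines: exact 95% binomial intervals). For 1 exon the shares are 35.2% and 22.5% in WT replicates 1 and 3 and 23.9% in cKO replicate 3, and at most 7.04% in the others.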

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

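The fits with depth batch or few-exon loss as a term, at equal depth, without both replicate 2 libraries, on autosomes or on genes with more than 3 exons were chosen after seeing the data. With RLE scaling, unrounded counts, a fold minimum of 1.5, limma-voom, limma on TPM, upper-quartile scaling and thinned counts, both counts stayed within 1.5 times 29 higher and 25 lower, but some genes differed in the last 4: of 39 and 30 called with upper-quartile scaling 22 and 20 were shared, of 43 and 33 on TPM 26 and 25, of 22 and 20 with limma-voom 19 and 20, and of 30 and 23 with thinned counts 28 and 22. DESeq2 called 250 and 179 genes. Without a filter, and with a filter of 1 CPM in 3 libraries that kept more genes (10524), 12 and 10 were called, all shared. With depth batch as a term 11 and 8 were called, with few-exon loss as a term 11 and 7, and with more than 3 exons 12 higher. With both replicate 2 libraries left out edgeR called 0 and 0 (740 genes at an unadjusted p below 0.05; no other tool was run). Leaving out 1 library gave 0 to 28 higher and 0 to 14 lower: 1 and 0 without WT replicate 1, 13 and 8 without WT replicate 2, 0 and 0 without WT replicate 3 or cKO replicate 1, 6 and 4 without cKO replicate 2, 28 and 14 without cKO replicate 3, with 7 and 7 shared without WT replicate 2 and 9 and 10 without cKO replicate 3. With the replicate number as a block 1 gene was higher and 0 lower (763 at an unadjusted p below 0.05). The labels state no pairing, so the main test had no block. Deviations of same-numbered libraries from their group means correlated with r = 0.064, 0.462 and 0.162. Both replicate 2 libraries and WT replicate 3, but not the others, correlated best with their own number. These values do not settle whether the numbers mark pairs. Interneurons passed with the block (camera adjusted p = 0.0228, but p = 0.513 with an estimated correlation). Mettl14 ranged from −0.51 to −1.66 without passing p of 0.05. Of 38 called genes recomputed (37 with thinned counts) 0 reversed, but the call ended for 38 without WT replicate 3, cKO replicate 1 or both replicate 2 libraries, for 37 with the block or without WT replicate 1, for 30 without cKO replicate 2, 26 without WT replicate 2, 23 without cKO replicate 3, 25 with either added term, 20 and 21 with no filter and the 1 CPM filter, 11 with limma-voom, 6 with upper-quartile scaling, 2 with thinned counts and 1 on TPM; Sox11, Zbtb18, Islr2, Dab1, Mt3 and Dbi were not among them. With the filter of 1 CPM the camera adjusted p was 0.0277 for axon cytoskeleton, 0.0229 for FMRP-bound mRNAs and for interneurons, 0.0361 for microglia and 0.0139 for mural cells, but adjusted p = 0.176 to 0.607 with an estimated correlation, chosen after seeing the data. An estimated correlation ended 10 list calls: camera adjusted p was 0.17 for m6A readers and excitatory neurons, 0.077 axon guidance, 0.423 glycolysis, 0.0711 precursors, 0.145 white-matter microglia, meningeal and upper-layer, 0.146 endothelial, 0.0502 radial glia. Leaving out 1 library, camera adjusted p ranged from 0.00715 to 0.123 for m6A readers, 0.00119 to 0.225 for glycolysis, 0.000119 to 0.0815 for white-matter microglia, 2.29e-05 to 0.105 for meningeal markers, 0.00024 to 0.666 for axon cytoskeleton and 0.0212 to 0.894 for the respiratory chain, which was called up without cKO replicate 3 (but p = 0.175 with an estimated correlation), against down and not called with all libraries. The causes were not tested. Fewer libraries or more genes tested can lower the power, but how far this accounts for the changed calls was not measured. Depth limits genes with few counts, such as Mettl14 (24 over WT, 11 over cKO).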

Other observations

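All tests of explanations here were chosen after the result was seen, except the splits of the libraries, the transcripts over 2 kb and the X-linked genes with more than 3 exons. A comparison of single called X-linked genes with a full second dose, and a count of calls on X and Y, were replaced by tests over all tested X-linked genes, since called genes are selected for their size. Intervals over libraries were added after the first values had been seen. Beyond the lists, Islr2, a membrane protein of growing axons, rose by 1.66 (SE 0.25) and Dab1, a protein of the reelin pathway, by 3.22 (SE 0.46) on the log2 scale, while Mt3, a metallothionein of brain, fell by 2.8 (SE 0.43) and Dbi by 2.63 (SE 0.36). Islr2 and Mt3 are among the genes with 1 to 3 exons.

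Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes in all as the genotypes did, the genotypes themselves, with 54 against a highest other of 41. Counted per direction, 2 of the 10 splits gave as many on their larger side, since that other split called 41 genes one way against 29 higher and 25 lower for the genotypes. It sets WT replicates 1 and 3 and cKO replicate 3 against the rest, the same libraries that lost few-exon genes; with that loss as a term, 11 and 7 genes were called, all shared with the calls without it. With 10 splits no share below 0.05 can be reached.

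Oligodendrocyte markers were far lower and several cortical neuron factors higher in cKO. A single lower share of all non-neuronal cells is argued against: oligodendrocyte markers lay 4.9 below microglial and endothelial markers (difference of medians −4.9, 95% interval over genes −9.1 to −2.06, over libraries −5.59 to −3.02). More cortical cell bodies in the cKO tissue may account for part of the neuronal rise; upper-layer less deep-layer medians differed by 1.31, with an interval over genes of −0.81 to 2.74 that includes 0 and leaves it open, and one over libraries of 0.04 to 2.56 that does not include 0. Loss of few-exon genes from single libraries could account for another part, since markers with more than 3 exons had a median of 0.51 (interval over genes −0.31 to 0.85, over libraries −0.44 to 1.31). Neurod2 was at 0 also in WT replicate 2, in which 7.62% of few-exon genes were at 0 or 1. That share cannot show whether Neurod2 itself was lost there. A difference in where each piece was dissected, a later start of oligodendrocyte maturation in cKO and the sex of the animals stay open and untested. A delay after the precursor stage alone would not lower precursor markers, yet all 8 tested had negative values (median −1.53), 1 past the threshold. As a list they did not pass with an estimated correlation (camera adjusted p = 0.0711), so such a delay is not excluded.

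Few-exon genes were more often at 0 or 1 count in WT replicates 1 and 3 and cKO replicate 3. Lower depth is argued against, since with counts thinned to equal depth the smallest gap to the other libraries was 10.2 percentage points. Its 95% interval over genes was 4.44 to 15.6. Few-exon genes were low together in the same libraries, so an interval over genes can be too narrow. The same pair, WT replicate 2 less cKO replicate 3 at −10.2, shows that the shares did not follow genotype in every library. It is 1 library of each group with genes as the unit, so the spread between libraries is not covered. Genotype as the whole cause is thus not excluded by it, and a contribution of genotype stays open. The loss was not limited to short transcripts. Among few-exon transcripts over 2 kb the shares at equal depth were 37.9%, 31.4% and 19.3% in these libraries. They were 10.7%, 5.71% and 2.86% in WT replicate 2 and cKO replicates 1 and 2. Over genes with more exons the smallest excess was 17.7 points (95% interval over genes 11.4 to 24.3). WT replicate 2 had an excess too (10.7% against 0.823%), and expression level was not matched, so an excess above 0 alone decides little. A step of library preparation or read assignment that treats unspliced reads differently is a candidate explanation that was not tested here.

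X-linked genes other than Xist lay above autosomal genes in cKO, by 0.59 in difference of medians on the log2 scale (interval over genes 0.34 to 0.92, over libraries 0.05 to 1.25). Among genes with more than 3 exons the difference was 0.52, with an interval over genes of 0.22 to 0.91. By the rule set beforehand, that interval argues against loss of few-exon genes as the whole source. The interval over libraries, −0.02 to 1.16, includes 0 and leaves that loss open. A full second dose, a difference near 1, is not excluded by the interval over libraries. Xist, the RNA of the inactive X chromosome, was counted in each cKO library. With an inactive X, sex alone would not give a full second dose of most X-linked genes. Values per library were −0.52, −0.47 and 0.09 in WT and 0.43, 0.15 and 0.46 in cKO. Sex and genotype are confounded here, so an effect of genotype on X-linked genes stays open and untested.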
